A study of Mus musculus with 35 samples.

How the data were processed

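Livers of 21 mice, labelled C57Bl6, were sequenced by the authors as 35 libraries with the QuantSeq 3' mRNA-Seq FWD kit on a NextSeq 500. The submitters named HISAT2 2.1.0 with the mm10 genome, and DESeq with no version. The program that counted the reads, its annotation and its filters are not stated. A deposited table gives raw counts for 55413 Ensembl genes, in which the authors had already merged the libraries of each ASO mouse into 1 column. A second table deposited by the authors holds a normalized score, the raw count divided by a median-of-ratios size factor over all 21 columns and rounded. This was checked against the raw table, and 100% of the values lay within 0.51 of that quotient. The raw counts were used throughout, and the deposited score only as an alternative.

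Mice were grouped by the sample labels as untreated at day 260 (5), DEN at day 133 (4), DEN with control ASO at day 260 (6) and DEN with Smyd3-ASO at day 260 (6). The libraries merged per mouse were 2 for each control-ASO mouse and 1 to 3 for a Smyd3-ASO mouse. Gene symbols, positions and biotypes came from GENCODE vM21 for mm10, and all 55413 genes matched. Genes were kept with edgeR filterByExpr over the 4 groups at once, which left 15297. The groups, the 5 comparisons, their tests, the gene lists, the rule for named genes and most alternatives were fixed before the data were examined, and 5 alternatives were added later.

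Each comparison was fitted on its own 2 groups with edgeR 4.0.16 in R 4.3.3, with TMM scaling, the robust quasi-likelihood fit and its two-sided test, and Benjamini-Hochberg adjustment over the 15297 genes. The threshold was an adjusted p of 0.05. Levels in counts-per-million units (CPM) are scaled with TMM over all 21 mice. Standard errors of log2 changes come from the same fits. Of 39 fixed gene lists, 36 had at least 5 measured members and were tested with camera in limma 3.58.1, with a preset correlation between genes of 0.01, adjusted over the 36 lists. Pancreas markers (2 measured), sex chromosome genes (4) and mitochondrial transcripts (0) were not tested. Among the list members, Ctgf, Ahsp and the mitochondrially encoded genes are not in the set that was tested and were not analysed here. In the lists that were called, the median, the mean and the direction from camera had the same sign in all 49 cases, and in those not called they differed in 32 of 131.

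Named genes were chosen by rule: Smyd3, then in each comparison the 10 largest rises and 10 largest falls past the threshold with a mean log2 CPM of at least 2, leaving out predicted or unnamed genes, and for each list discussed the 4 members with the smallest adjusted p. Some genes that the rule takes are not given in the text. Members of a list that moved against the rest of it, members of other lists given beside a count of 5 or fewer, the other Smyd genes and Glul were named after their values were seen. A fold against a group with 0 counts is taken at 3 counts over the group and given with the lower limit of an exact Poisson 95% interval. With 1 to 3 counts over a group the ratio of summed counts is given with an exact Poisson 95% interval. These intervals and limits cover counting error only, since reads carry no molecular identifiers. The level of Smyd3 was also compared with an exact two-sided permutation test over all splits of the mice.

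The return of altered genes toward untreated levels was scored with limma on log2 CPM with a prior count of 2. The 6 control-ASO mice were split into 3 and 3 in all 20 ordered ways. Genes that differed between 3 of them and untreated mice, at an adjusted p of 0.05 and 1.5-fold or more, were scored in Smyd3-ASO mice against the other 3. The score was compared with 100 splits of the ASO mice. Counts of genes and lists were compared in the same way with 100 splits of the mice of each comparison.

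The calls were tested on simulated data with the spread and depth of these mice. In the simulation 66 or 67 genes changed at each fold, besides the cell cycle list, far fewer than were called in the data. Adjustment is stricter when few genes change, so the shares recovered may understate those in the data. For Smyd3-ASO against control ASO, 4.5% of genes changed 1.5-fold, 35.8% of those changed 2-fold and 92.4% of those changed 4-fold were recovered, and 5% of calls were false. For control ASO over untreated, Smyd3-ASO over untreated, P133 over untreated and control ASO over P133, 83.3, 89.4, 69.7 and 75.8% of 4-fold changes were recovered, and 3.4, 7, 4.8 and 9% of calls were false. The simulated return score was -0.005 (permutation p = 0.38) with no return and 0.693 (permutation p = 0.01) with a partial return built in.

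Total counts per mouse ran from 4556484 to 20258619. The 10 most abundant genes held 24.9 to 32.2% of counts in untreated, 17.4 to 19.1% in P133, 17.3 to 22.9% in control-ASO and 9.46 to 15.7% in Smyd3-ASO mice. Of 9863 genes with more than 1000 counts in all, 82 had counts identical to another gene in every mouse, so the table may count some reads for more than 1 gene.

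Alternatives changed 1 choice at a time, except that DESeq2 and limma on the deposited score changed both test and scaling, and voom with sample weights both test and weights. The block on replicate number also dropped mice whose number the other group lacks. The alternatives were size factors in place of TMM, no filter, a stricter filter at 1 CPM, thinning to the lowest total, limma voom with and without sample weights, DESeq2 1.42.0, limma on the deposited score, all groups in 1 fit, replicate number as a block, leaving out each mouse, camera with an estimated correlation, fry, and for the return score other fold minimums, a prior count of 5 and the stricter filter. Added later were library totals, protein-coding genes only, mice with high acute-phase genes left out, mice with shifted clock genes left out, and removal of each mouse's trend on GC content in the last 500 bases of transcripts. Replicate numbers did not pair the mice, as correlations between mice of the same number ran from -0.12 to 0.112. Alternatives on single technical replicates could not be run on merged columns. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.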

Results

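Liver RNA of 21 mice was measured by 3' end sequencing, in which each read comes from the end of a polyadenylated transcript. The mice received no treatment, or an injection of diethylnitrosamine (DEN, a liver carcinogen) at 25 mg/kg on day 14 after birth. The 5 untreated mice were harvested at day 260. A group of 4 DEN mice was harvested at day 133 and is called P133. The other DEN mice were injected 2 times a week from day 133 with an antisense oligonucleotide (ASO, a short synthetic strand that pairs with a target RNA) at 50 mg/kg and harvested at day 260. Of these, 6 received a control ASO and 6 received an ASO against Smyd3. The labels name all DEN samples as tumour and the untreated samples as normal liver. Each mouse had 1 column of counts, in which the sequencing libraries of an ASO mouse were already added together. Total counts ran from 10186780 to 13116012 in untreated mice, from 4556484 to 6447397 in P133 mice, from 6789715 to 13805881 in control-ASO mice and from 6358080 to 20258619 in Smyd3-ASO mice. Of 55413 genes, 15297 passed the filter on low counts and were tested in every comparison. Levels are given in counts-per-million units (CPM) with the standard deviation (SD) over mice, and changes as log2 fold changes from edgeR with their standard error (SE).

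The aim in the title of the series concerns lowering Smyd3, a lysine methyltransferase, in liver tumours, so its own RNA was read in every group. Smyd3 (ENSMUSG00000055067; protein-coding, mm10 chromosome 1, minus strand, 178951960 to 179518041) stood at 0.325 ± 0.289 CPM (SD, n = 6) under Smyd3-ASO and at 3.87 ± 0.598 CPM (n = 6) under control ASO. This was a 12.6-fold fall (log2 -3.65, SE 0.47, adjusted p = 1.48e-04). The highest Smyd3-ASO mouse, at 0.758 CPM, lay below the lowest control-ASO mouse, at 3.11 CPM. An exact two-sided permutation test gave p = 0.00216, the smallest that 924 splits of 12 mice allow. Raw Smyd3 counts were few, 0 to 13 per mouse under Smyd3-ASO and 29 to 68 under control ASO. The mouse with 0 counts allows a level of up to 0.162 CPM. In the other groups Smyd3 stood at 3.82 ± 1.10 CPM (SD, n = 5) in untreated livers and 4.25 ± 1.17 CPM (n = 4) in P133 livers. Control ASO over untreated was log2 0.03 (adjusted p = 0.929) and P133 over untreated was log2 0.16 (adjusted p = 0.694), neither past the threshold. With library totals in place of TMM scaling these became log2 0.88 (adjusted p = 0.00261) and log2 0.77 (adjusted p = 0.04), next to shifts of all genes by a median of 0.85 and 0.59. Of the 5 members of the Smyd family that were measured, Smyd3 fell and the others did not pass. Smyd2 was at log2 -0.30 (adjusted p = 0.306), Smyd5 at 0.15 (adjusted p = 0.639) and Smyd1 at -0.17 (adjusted p = 0.776).

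**Figure D1:**
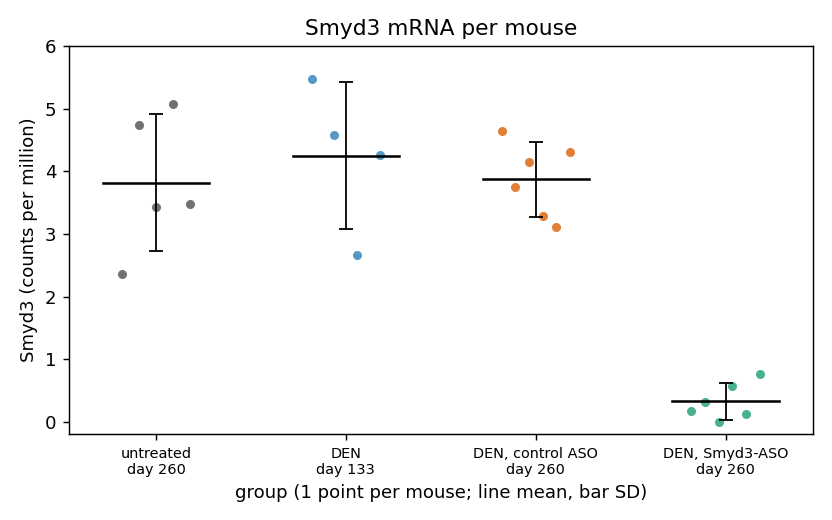
Smyd3 level of each of the 21 mice in CPM on a linear axis, by group, with group means and standard deviations as bars. All 6 Smyd3-ASO mice lie at or below 0.758 and all 6 control-ASO mice at or above 3.11.

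Smyd3-ASO against control ASO asks what differs in DEN livers of the same age when Smyd3 is targeted. Of 23 oncofetal and liver tumour markers 12 fell and 4 rose under Smyd3-ASO, a call that ended with an estimated correlation between genes (adjusted p = 0.627). Gpc3, a fetal cell-surface proteoglycan and liver cancer marker (ENSMUSG00000055653, chromosome X), stood at 3.25 ± 1.92 CPM against 67.1 ± 40.9 (SD, n = 6 each; log2 -4.39, SE 0.52, adjusted p = 1.60e-04) and at 0.757 ± 0.392 CPM in untreated livers. Afp, the fetal serum protein alpha-fetoprotein (ENSMUSG00000054932, chromosome 5), fell from 183 ± 84.8 to 22.3 ± 13.7 CPM (log2 -3.05, SE 0.49, adjusted p = 9.77e-04), against 3.95 ± 1.34 in untreated livers. Of 21 female-biased liver genes 15 fell and 2 rose, of 18 pericentral genes 6 rose and 1 fell, and of 22 fatty acid oxidation genes 9 rose and 2 fell. Of the 7 lists called, the female-biased list alone kept its call with an estimated correlation. In all, 2028 genes rose, 1972 fell and 11297 did not pass, so 26.1% of the genes tested were called. With limma voom 1883 rose and 2117 fell.

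Each fixed gene list was tested against all other genes with camera, and 7 of 36 were called, 3 up and 4 down. Oncofetal and liver tumour markers had 23 measured members, of which 4 rose, 12 fell and 7 did not pass, while adjusted over the list alone 4 rose and 13 fell. The list moved down (camera adjusted p = 0.00125; adjusted p = 0.627 with an estimated correlation). Golm1, a Golgi protein released by liver tumours, fell (log2 -2.33, SE 0.35, adjusted p = 4.34e-04), as did Tff3, a mucosal peptide (log2 -3.66, SE 0.58, adjusted p = 9.83e-04). The 4 that rose were Cbr3 (log2 2.31), Abcc4 (1.08), Rgs5 (0.91) and Cd44 (0.78). Female-biased liver genes had 21 members, of which 15 fell, 2 rose and 4 did not pass, while adjusted over the list alone 16 fell and 2 rose. This list moved down (camera adjusted p = 3.59e-09) and kept its call with an estimated correlation (adjusted p = 0.0311). Cyp2b9, a cytochrome normally higher in females (ENSMUSG00000040660, chromosome 7), fell from 13.9 ± 3.63 to 0.759 ± 0.486 CPM (log2 -4.15, SE 0.38, adjusted p = 1.84e-05). Cyp2a4, a steroid hydroxylase, fell from 721 ± 313 to 36.6 ± 21.4 CPM (log2 -4.31, SE 0.52, adjusted p = 1.55e-04). Abcd2, a peroxisomal transporter, and the cytochrome Cyp3a41b fell by 3.17 and 4.76 on the log2 scale. The 2 that rose were Cyp2b10 and the estrogen sulfotransferase Sult1e1, both by log2 3.60. Male-biased genes did not pass as a list, with 3 of 21 up and 0 down (camera adjusted p = 0.0565).

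Genes of the pericentral hepatocyte, which depend on Wnt signalling, were higher under Smyd3-ASO. Of 18 measured, 6 rose, 1 fell and 11 did not pass, while adjusted over the list alone 10 rose and 1 fell (camera adjusted p = 0.00159; adjusted p = 0.627 with an estimated correlation). Cyp27a1, a sterol hydroxylase of bile acid synthesis (ENSMUSG00000026170, chromosome 1), rose from 54.2 ± 13.2 to 207 ± 22.2 CPM (SD, n = 6 each; log2 1.92, SE 0.16, adjusted p = 7.99e-06), next to 223 ± 21.7 in untreated livers. Oat, ornithine aminotransferase, rose by log2 1.62 (SE 0.39) and Cyp2e1, the ethanol-oxidising cytochrome, by 1.22 (SE 0.33), while the transcription factor Tcf7 fell (log2 -1.04, SE 0.28), a call that ended without the filter (adjusted p = 0.0514), with thinning (0.0503) and with a replicate block (0.0553). Fatty acid oxidation genes, targets of PPAR alpha, had 9 of 22 up, 2 down and 11 not passed, while adjusted over the list alone 10 rose and 2 fell (camera adjusted p = 0.0308; adjusted p = 0.755 with an estimated correlation). Acot1, Slc25a20 and Cyp4a10 rose by log2 1.45, 0.77 and 2.14, and the fasting hormone Fgf21 and the receptor Ppara fell (log2 -3.77 and -0.79). Targets of NRF2, the activator of antioxidant genes, had 7 of 20 up, 1 down (G6pdx, log2 -0.94) and 12 not passed, with the same counts of 7 and 1 adjusted over the list alone (camera adjusted p = 0.0368; adjusted p = 0.789 with an estimated correlation). The glutathione transferases Gsta1 and Gstm2 rose by log2 4.37 (SE 0.84) and 1.84 (SE 0.42), thioredoxin reductase Txnrd1 by 0.68 and the epoxide hydrolase Ephx1 by 1.08. The call of Gstm2 ended with a replicate block (adjusted p = 0.0504). The call of fatty acid oxidation ended without control-ASO mouse 6 (adjusted p = 0.0517) or Smyd3-ASO mouse 6 (0.0913). That of the NRF2 list ended without control-ASO mice 1 or 2 (adjusted p = 0.0679 and 0.0661), without Smyd3-ASO mice 2 or 6 (0.067 and 0.0913), with library totals (0.0531), with a block on replicate number (0.0785), with fry (0.114) and without the mice of shifted clock genes (0.104).

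Secreted hepatocyte proteins were lower under Smyd3-ASO, with 10 of 20 down, 0 up and 10 not passed, and 11 down adjusted over the list alone (camera adjusted p = 5.73e-05; adjusted p = 0.627 with an estimated correlation). Alb, which encodes serum albumin, fell from 46236 ± 6433 to 20135 ± 5898 CPM (SD, n = 6 each; log2 -1.21, SE 0.22, adjusted p = 0.00139). The plasma protein genes Ahsg, Serpina1b and Apoa1 fell by 2.25, 2.33 and 1.60 on the log2 scale (SE 0.25, 0.29 and 0.26). This list was also called down in P133 over untreated livers, where no ASO was given (11 of 20 down; adjusted p = 0.813 with an estimated correlation), and did not pass in control ASO over untreated (camera adjusted p = 0.243). Erythroid markers moved down, with 3 of 6 down, 1 up and 2 not passed, while adjusted over the list alone 4 fell and 1 rose (camera adjusted p = 0.0236; adjusted p = 0.627 with an estimated correlation). The globin genes Hbb-bs, Hba-a1 and Hbb-bt fell by 2.18, 1.89 and 1.25 on the log2 scale (SE 0.30, 0.27 and 0.24). Erythroid markers too were called down in P133 over untreated livers (5 of 6 down; adjusted p = 0.813 with an estimated correlation) and did not pass in control ASO over untreated (camera adjusted p = 0.101). Alas2, the erythroid enzyme that starts haem synthesis, was at log2 0.72 (SE 0.25, adjusted p = 0.043), a call that ended without any 1 of control-ASO mice 2, 4, 5 and 6 or of Smyd3-ASO mice 1, 3, 4, 5 and 6 (adjusted p up to 0.0907).

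**Figure D2:**
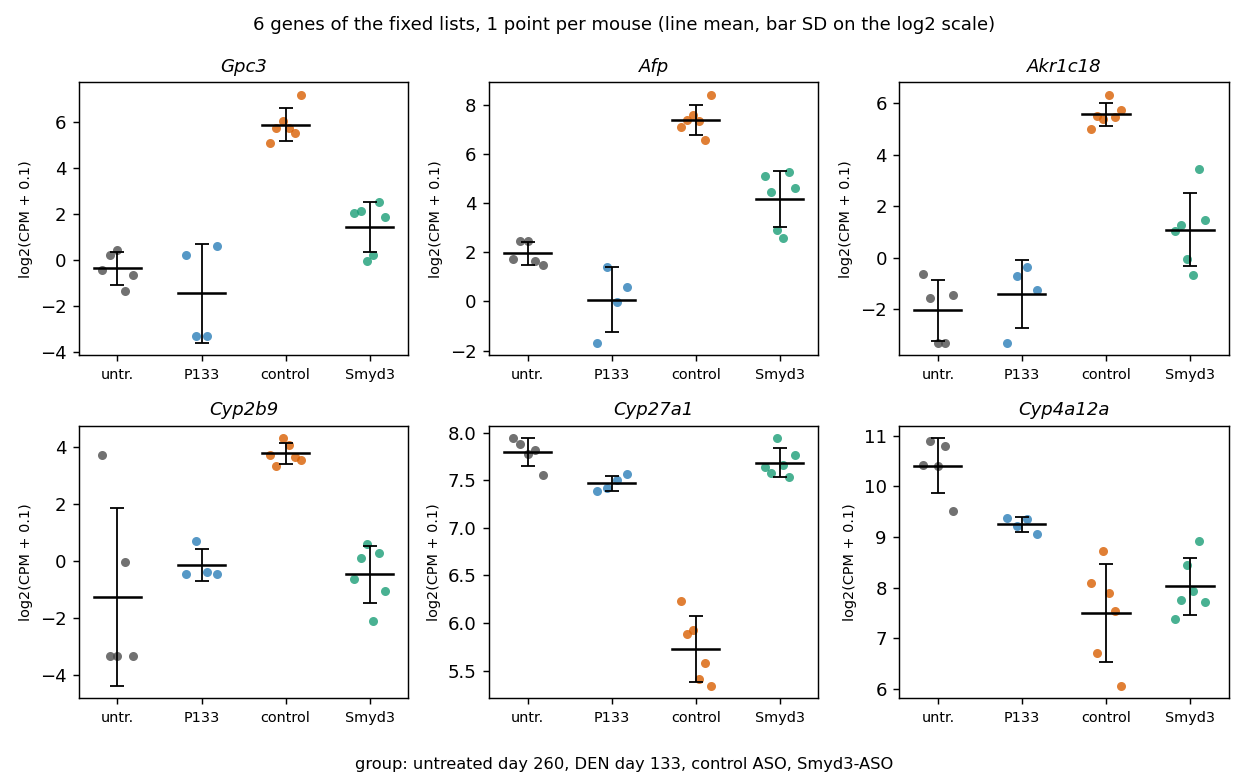
Levels of Gpc3, Afp, Akr1c18, Cyp2b9, Cyp27a1 and Cyp4a12a in each of the 21 mice, as log2 of CPM plus 0.1, by group, with lines at group means and bars of 1 standard deviation. Cyp2b9 averages 13.9 CPM in control-ASO and 0.759 in Smyd3-ASO mice.

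**Figure D3:**
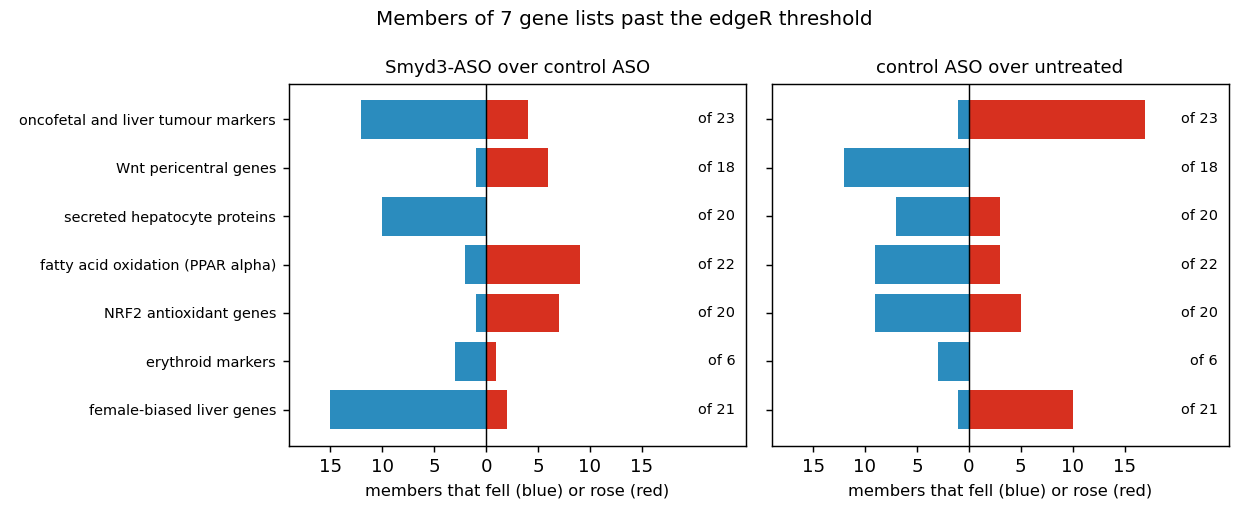
Number of measured members of 7 gene lists that rose (red bars, to the right) or fell (blue bars, to the left) past the edgeR threshold, for Smyd3-ASO over control ASO and for control ASO over untreated, with the number measured beside each bar. Of 21 female-biased genes 15 fell in the former comparison and 10 rose in the latter.

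Among single genes, the largest rises past the threshold at a mean log2 CPM of at least 2 included Mug2, a murinoglobulin protease inhibitor (ENSMUSG00000030131, chromosome 6), which went from 16.9 ± 7.09 to 197 ± 32.7 CPM (SD, n = 6 each; log2 3.53, SE 0.26, adjusted p = 4.71e-06). Also among them were the transcription factor Olig1 (log2 3.92, SE 0.46), the interferon-induced membrane protein Bst2 (4.07, SE 0.91), the complement protease Cfd (4.91, SE 1.16), Gsta1, Sult1e1 and Odf3 (4.45, SE 1.18). The largest falls were those of Lrrc24 (log2 -6.30, SE 0.52), the noncoding Nctc1 (-5.83, SE 1.27), the protease Ctse (-5.75, SE 0.53), Cyp2b13 (-5.73, SE 0.76), the cholesterol hydroxylase Cyp46a1 (-5.71, SE 0.99), Mir675, which is processed from the H19 transcript (-5.62, SE 1.34), Crym (-5.44, SE 0.60), Cyp3a16 (-5.28, SE 0.78), Ly6k (-5.15, SE 0.85) and Cyp3a41a (-5.13, SE 0.64). Saa3, Socs1 and Tifa, with log2 rises of 4.94, 3.68 and 3.68, rested on Smyd3-ASO mouse 3 and dropped to 1.58 (adjusted p = 0.156), 0.96 (0.221) and 1.98 (0.0742) without it. Their calls also ended without single control-ASO mice (2 to 6 for Saa3, adjusted p up to 0.0627; 1 to 6 for Socs1, up to 0.089; 4 or 5 for Tifa, up to 0.0529). With limma voom Saa3 (2.37, adjusted p = 0.176), Cfd (5.15, 0.0962) Odf3 (2.84, 0.148), Socs1 (1.93, 0.302), Tifa (1.86, 0.147) and Cyp46a1 (-4.58, 0.061) did not pass, and with sample weights Mir675 (adjusted p = 0.0805) and Ly6k (0.0812) did not either. Single mice moved other changes by over 1.5 times. Without control-ASO mice, Nctc1 stood at -4.00 (without mouse 3), Mir675 at -3.85 (mouse 6), Bst2 at 5.66 (mouse 4), and Saa3 and Cfd at 5.69 and 5.71 (mouse 1). Without Smyd3-ASO mice, Odf3 stood at 3.54 and Cfd at 4.25 (mouse 6), Nctc1 and Mir675 at -6.85 and -7.49 (mouse 1), Ctse at -6.39 (mouse 2), Tff3 at -4.27 (mouse 4), and Cyp2b13 and Cyp3a16 at -6.36 and -6.12 (mouse 5).

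Some genes set the groups apart in pairs. In 21 genes on 12 chromosomes, chosen after their values were seen, every untreated and control-ASO mouse was separated from every P133 and Smyd3-ASO mouse by an empty gap of at least 2-fold. The gap put 14 genes higher in untreated and control-ASO livers and 7 higher in P133 and Smyd3-ASO livers. Ctse (ENSMUSG00000004552, chromosome 1) stood at 14.4 ± 4.62 CPM (SD, n = 5) in untreated, 0.222 ± 0.213 (n = 4) in P133, 10.3 ± 3.49 (n = 6) in control-ASO and 0.189 ± 0.188 (n = 6) in Smyd3-ASO livers. Mug2 stood at 7.97 ± 3.25, 179.5 ± 13.1, 16.9 ± 7.09 and 197 ± 32.7 CPM in the same order. All 21 were among the genes called between Smyd3-ASO and control ASO, and 11 were pseudogenes, against 9.04% of the genes tested. The 2 other ways of pairing the groups gave 2 and 0 such genes. Without overlap of any size were 177 genes, against 419 with untreated and P133 mice on 1 side and 82 with untreated and Smyd3-ASO mice on 1 side, where a chance parting of 11 and 10 mice leaves 5.67e-04% of genes. In 100 random splits of the 12 ASO mice, 88 called as many lists as the real split, itself included. With replicate number as a block 3092 genes were called.

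Control ASO against untreated compares tumour-bearing with normal livers of the same harvest day, and DEN cannot be separated from the ASO injections here. Oncofetal (17 of 23 members), Ras-MAPK feedback (7 of 11), immediate early (14 of 19), p53 target (10 of 18), bile duct (6 of 10) and female-biased genes (10 of 21) rose, and pericentral (12 of 18), urea cycle (13 of 20), bile acid (12 of 19) and male-biased genes (14 of 21) fell. Of these 10 lists 0 kept the call with an estimated correlation. Akr1c18, a progesterone-degrading reductase (ENSMUSG00000021214, chromosome 13), rose from 0.208 ± 0.223 CPM (SD, n = 5) to 49.5 ± 16.8 (n = 6; log2 7.67, SE 0.45, adjusted p = 1.92e-07), and Afp from 3.95 ± 1.34 to 183 ± 84.8 CPM (log2 5.53, SE 0.37, adjusted p = 5.15e-07). Cyp4a12a, a male-biased fatty acid hydroxylase (ENSMUSG00000066071, chromosome 4), fell from 1432 ± 463 to 215 ± 128 CPM (log2 -2.74, SE 0.43, adjusted p = 3.35e-04). In all, 3620 genes rose, 3398 fell and 8279 did not pass, a call for 45.9%.

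Of 36 lists 10 were called, 6 up and 4 down. Oncofetal and liver tumour markers had 17 of 23 up, 1 down (Igf2bp3, log2 -2.07) and 5 not passed, with 17 and 1 adjusted over the list alone (camera adjusted p = 4.42e-10; adjusted p = 0.217 with an estimated correlation). Gpc3 rose by log2 6.45 (SE 0.52) and the stem cell marker Prom1 by 3.53 (SE 0.33). Feedback genes of Ras-MAPK signalling had 7 of 11 up and 4 not passed, with 7 up adjusted over the list alone (camera adjusted p = 4.93e-04; adjusted p = 0.349 with an estimated correlation). The phosphatase gene Dusp6 rose from 26.4 ± 3.71 to 125 ± 40.3 CPM (log2 2.25, SE 0.21), Dusp5 by 4.56, the Ras inhibitor Spred1 by 1.10 and the transcription factor Etv5 by 1.63. Immediate early genes, the first transcribed after a stimulus, had 14 of 19 up and 5 not passed, with 14 up adjusted over the list alone (camera adjusted p = 1.39e-05; adjusted p = 0.403 with an estimated correlation), among them Klf6 (log2 2.96, SE 0.21), Junb (2.58), Ier2 (1.74) and Ier3 (2.51). Targets of p53 had 10 of 18 up, 1 down (Perp, log2 -0.61) and 7 not passed, with 10 and 1 adjusted over the list alone (camera adjusted p = 0.00348; adjusted p = 0.403 with an estimated correlation). The apoptosis gene Bax rose by log2 1.92 (SE 0.23), the cell cycle inhibitor Cdkn1a by 2.47 (SE 0.43), Btg2 by 3.05 and Plk2 by 1.33. Bile duct cell markers had 6 of 10 up and 4 not passed, with 6 up adjusted over the list alone (camera adjusted p = 6.74e-04; adjusted p = 0.349 with an estimated correlation). Tspan8, a membrane protein, rose from 0.128 ± 0.123 to 63.8 ± 28.5 CPM, the duct transcription factor Sox9 by log2 2.72 and osteopontin, Spp1, by 1.92. Cldn7, with 2 counts in the untreated group, was 44.4-fold higher (95% counting interval 12.1 to 370).

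Of the lists that moved down, the pericentral genes had 12 of 18 down, 0 up and 6 not passed, with 13 down adjusted over the list alone (camera adjusted p = 1.19e-04; adjusted p = 0.421 with an estimated correlation). Cyp1a2 and Cyp2e1, drug-oxidising cytochromes, fell by 3.16 and 1.87 on the log2 scale, Cyp27a1 by 2.04 and the ammonium transporter Rhbg by 1.5. Urea cycle and amino acid breakdown genes had 13 of 20 down, 0 up and 7 not passed, with 14 down adjusted over the list alone (camera adjusted p = 1.56e-05; adjusted p = 0.403 with an estimated correlation). Proline dehydrogenase, Prodh, fell by 2.16 (SE 0.21), Haao by 1.94, Sds by 1.5 and the urea cycle enzyme Ass1 by 1.28 on the log2 scale. Bile acid genes had 12 of 19 down, 1 up (Abcc4, log2 1.55) and 6 not passed, while adjusted over the list alone 15 fell and 1 rose (camera adjusted p = 1.39e-05; adjusted p = 0.403 with an estimated correlation). The bile acid enzyme Akr1d1 fell by 2.52, the uptake carrier Slc10a1 by 1.59 and the export pump Abcb11 by 0.98, the last of which did not pass with library totals (log2 -0.15, adjusted p = 0.393). Male-biased liver genes had 14 of 21 down, 0 up and 7 not passed, with 17 down adjusted over the list alone (camera adjusted p = 2.93e-06; adjusted p = 0.403 with an estimated correlation). Ugt2b38, Nudt7 and Cyp2d9 fell by 4.17, 2.04 and 1.84 on the log2 scale. Female-biased genes moved up, with 10 of 21 up, 1 down (Cyp2b10, log2 -3.03) and 10 not passed, while adjusted over the list alone 11 rose and 1 fell (camera adjusted p = 3.53e-04; adjusted p = 0.403 with an estimated correlation). Cyp2a4 rose from 5.15 ± 6.01 to 721 ± 313 CPM, Cyp3a41b by log2 5.52 and Cyp39a1 by 2.15, and Cyp2b13, with 1 count in the untreated group, was 260-fold higher (46.5 to 10307). With library totals the female-biased list did not pass (adjusted p = 0.42), and 10723 genes were called, 93.6% of them up. With an estimated correlation 0 of the 36 lists passed after adjustment, 3 had an unadjusted camera p under 0.05, and fry called 19.

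Several of the largest rises came from untreated levels of 0 counts, where 3 counts over the group correspond to 0.0779 CPM. At 3 counts Gldn was 223-fold higher (lower 95% counting limit 181), Erich4 217-fold (176) and Prom2 179-fold (145). Shc2 was 141-fold higher (114), Kif5c 117-fold (95.3) and Dlk1, a fetal Notch ligand, 109-fold (88.4). Nctc1, with 1 count in the untreated group, was 371-fold higher (95% counting interval 66.4 to 14681). The imprinted fetal transcript H19 rose from 0.757 ± 1.22 to 258 ± 197 CPM (SD, n = 5 and 6; log2 8.24, SE 1.07) and Wfdc15b by 8.18 (SE 0.84). The largest falls included Odf3 (log2 -6.61, SE 1.10), Cyp4a12b (-4.58, SE 0.84), Ugt2b38, Gbp11 (-4.13, SE 0.56) and the major urinary protein genes Mup17 (-4.84, SE 1.47), Mup18 (-4.71, SE 1.35) and Mup11 (-4.26, SE 1.45). Tph1 (-5.18), Orm2 (-4.98) and Saal1 (-4.59) rested on untreated mouse 5 and stood at -1.47 (adjusted p = 0.255), -1.91 (0.122) and -0.86 (0.475) without it. Mup17 without untreated mouse 3 was at -3.05 (adjusted p = 0.0686) and Mup11 at -2.97 (0.101), while Mup11 and Nctc1 also ended without untreated mouse 5 (adjusted p = 0.0516 and 0.0727) and Dlk1 without control-ASO mouse 1 (0.0503). Calls of Tph1, Saal1 and Mup11 further ended without any 1 of control-ASO mice 2 to 6, and that of Orm2 without mouse 6 (adjusted p up to 0.0832). With limma voom Dlk1 (adjusted p = 0.078), Nctc1 (0.0708) and Tph1 (0.14) did not pass, and with a replicate block Mup17 (0.114), Mup18 (0.0902) and Mup11 (0.0868) did not. Without control-ASO mouse 3 Nctc1 was 132-fold higher, and without mouse 5 Dlk1 was 65.9-fold higher at 3 counts in the untreated group. Mup18 stood at log2 -3.41 without untreated mouse 3. Without untreated mouse 1 H19 stood at 10.01, Wfdc15b at 9.48, Akr1c18 at 8.38, Cyp3a41b at 6.54 and Cyp2a4 at 8.17. Without control-ASO mouse 1 Tph1 (-6.70), Orm2 (-5.84), Saal1 (-6.02), Mup17 (-5.97), Mup18 (-5.57) and Mup11 (-6.26) stood lower, as did Cyp4a12b (-5.23) without mouse 3. In 100 random splits of the 11 mice, 70 called as many lists as the real split. With replicate number as a block 5712 genes were called.

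Smyd3-ASO against untreated asks what still differed from normal liver. Immediate early genes (14 of 19) and p53 targets (12 of 18) were higher, and secreted protein (13 of 20), erythroid (6 of 6) and male-biased genes (11 of 21) were lower. Of the 8 lists called 0 kept the call with an estimated correlation. Serpina1b, an antitrypsin gene (ENSMUSG00000071178, chromosome 12), fell from 27872 ± 6693 CPM (SD, n = 5) to 1829 ± 714 (n = 6; log2 -3.95, SE 0.33, adjusted p = 1.76e-06). The beta-globin gene Hbb-bs fell from 1943 ± 642 to 223 ± 72.2 CPM (log2 -3.14, SE 0.29, adjusted p = 3.04e-06). Egr1, an early response transcription factor, rose from 4.15 ± 4.28 to 210.1 ± 118 CPM (log2 5.62, SE 0.80, adjusted p = 2.43e-04). In all, 3734 genes rose, 3554 fell and 8009 did not pass, a call for 47.6%.

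The 8 lists called were 3 up and 5 down. Oncofetal and liver tumour markers had 13 of 23 up, 1 down (Igf2bp3, log2 -4.03) and 9 not passed, while adjusted over the list alone 14 rose and 1 fell (camera adjusted p = 0.00188; adjusted p = 0.468 with an estimated correlation), among them Rgs5 (log2 2.14, SE 0.22), the protease inhibitors Slpi (3.53) and Spink1 (2.39). Targets of p53 had 12 of 18 up, 1 down (Perp, log2 -0.93) and 5 not passed, while adjusted over the list alone 13 rose and 1 fell (camera adjusted p = 5.16e-04; adjusted p = 0.468 with an estimated correlation). The nuclease gene Aen rose by log2 1.94, the stress hormone Gdf15 by 3.80, Eda2r by 3.76 and the p53 ligase Mdm2 by 0.98. Immediate early genes had 14 of 19 up and 5 not passed, with 14 up adjusted over the list alone (camera adjusted p = 2.25e-04; adjusted p = 0.468 with an estimated correlation), among them Fos (log2 4.88, SE 0.47), Junb (3.58) and Klf6 (3.41). Secreted hepatocyte proteins had 13 of 20 down, 1 up (Apob, log2 1.76) and 6 not passed, with 13 and 1 adjusted over the list alone (camera adjusted p = 2.25e-04; adjusted p = 0.468 with an estimated correlation). The clotting factor gene F9, Ahsg and the thyroxine carrier Ttr fell by 2.04, 2.43 and 2.58 on the log2 scale. Urea cycle and amino acid breakdown genes had 10 of 20 down, 0 up and 10 not passed, with 10 down adjusted over the list alone (camera adjusted p = 0.0159; adjusted p = 0.524 with an estimated correlation), among them Prodh (log2 -2.14), Hpd (-1.75), Cps1 (-1.12) and Otc (-0.93). Bile acid genes had 9 of 19 down, 1 up (Abcc4, log2 2.62) and 9 not passed, with 9 and 1 adjusted over the list alone (camera adjusted p = 0.00188; adjusted p = 0.468 with an estimated correlation). Akr1d1, Slc10a1, Slco1a4 and Hsd3b7 fell by 2.22, 1.95, 2.42 and 1.30 on the log2 scale.

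All 6 erythroid markers measured fell, with 6 adjusted over the list alone (camera adjusted p = 2.64e-04; adjusted p = 0.468 with an estimated correlation), including Hba-a1 (log2 -2.61), Hbb-bt (-2.06) and Alas2 (-0.99). Male-biased liver genes had 11 of 21 down, 0 up and 10 not passed, with 11 down adjusted over the list alone (camera adjusted p = 0.00297; adjusted p = 0.612 with an estimated correlation). Cyp4a12a, Nudt7, Hsd3b5 and Slco1a1 fell by 2.38, 1.79, 3.28 and 2.41 on the log2 scale. Among single genes Cfd, with 1 count in the untreated group, was 1097-fold higher (95% counting interval 197 to 43336) and the lipid droplet gene Cidea, with 3 counts, 83.4-fold (28.4 to 405). Other large rises were Mir3092 (log2 6.92, SE 1.14), the chemokine Cxcl1 (6.47, SE 1.36), Sult1e1 (5.96, SE 1.06), the ubiquitin-like Ubd (5.42, SE 1.32), Bst2 (5.38, SE 0.98), Cd300ld (5.34, SE 0.33) and Cyp21a1 (5.34, SE 1.59). With limma voom Cfd (adjusted p = 0.116), Cidea (0.071), Ubd (0.147) and Cyp21a1 (0.118) did not pass. The largest falls were Ctse (log2 -6.25, SE 0.52), Serpina3h (-5.17, SE 0.64), Hamp2 (-5.05, SE 0.98), Serpina3c (-4.76, SE 0.39), Cyp46a1 (-4.45, SE 1.09), Nrep (-4.01, SE 0.54), Plag1 (-3.96, SE 0.40), C1s2 (-3.90, SE 0.81) and Tnfsf10, a death receptor ligand (-3.65, SE 0.21). Of these Ctse, Serpina3h, Serpina3c and Tnfsf10 are among the 21 genes parted by group pair, and Ctse and Tnfsf10 stood at 10.3 and 12.9 CPM in control-ASO livers, against 14.4 and 19.2 in untreated livers. Cyp46a1 stood at -2.63 without untreated mouse 4, Hamp2 at -3.87 and Bst2 at 6.83 without untreated mouse 1, Egr1 at 6.49 without untreated mouse 2, Mir3092 at 7.64 without untreated mouse 3 and Sult1e1 at 6.62 without untreated mouse 5. Without Smyd3-ASO mouse 3 Cyp21a1 stood at 3.13, Cxcl1 at 5.14, Mir3092 at 6.18 and Serpina3h at -6.53, without mouse 2 Ctse at -6.88 and without mouse 5 C1s2 at -5.54. The call of Cyp46a1 ended with voom and sample weights (adjusted p = 0.0962) and with a replicate block (0.0684). With library totals the oncofetal and urea cycle lists did not pass (adjusted p = 0.232 and 0.0622), nor did Cps1 (0.242), Otc (0.891), Hsd3b7 (0.122) and Alas2 (0.648), and 10415 genes were called, 91.4% of them up. With an estimated correlation 0 lists passed after adjustment, 2 had an unadjusted camera p under 0.05, and fry called 23. In 100 random splits of the 11 mice, 76 called as many lists as the real split, and 6986 genes were called with replicate number as a block.

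The question whether genes altered in control-ASO livers lay nearer to untreated levels under Smyd3-ASO was asked with separate control mice for choosing and for scoring genes. On average 4714.8 genes were chosen. They stood 0.17 log2 units nearer to untreated under Smyd3-ASO (0.061 to 0.248 over the ways of splitting the controls), with a two-sided permutation p = 0.08 over 100 splits of the ASO mice, where the highest other split gave 0.236. This did not pass. The score passed with a 2-fold minimum for choosing genes (0.257, p = 0.02), and without Smyd3-ASO mouse 1 (0.19, p = 0.03), mouse 2 (0.2, p = 0.01) or mouse 4 (0.181, p = 0.04), or without untreated mouse 2 (0.191, p = 0.04), each by permutation.

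P133 against untreated sets DEN livers at the start of ASO injections against older normal ones, so DEN, age and time of day cannot be separated. Cholesterol synthesis (12 of 21), secreted protein (11 of 20), extracellular matrix (9 of 25), erythroid (5 of 6) and cell cycle genes (9 of 28) were lower in P133 livers. With an estimated correlation 0 of these 5 lists kept the call (adjusted p from 0.813 to 0.91). Dhcr7, the last enzyme of cholesterol synthesis (ENSMUSG00000058454, chromosome 7), stood at 12.0 ± 2.23 CPM (SD, n = 4) against 64.1 ± 20.1 (n = 5; log2 -2.41, SE 0.22, adjusted p = 3.59e-06). Serpine2, a protease inhibitor (ENSMUSG00000026249, chromosome 1), was higher, at 33.3 ± 3.99 against 1.4 ± 0.590 CPM (log2 4.58, SE 0.24, adjusted p = 4.33e-08). In all, 2306 genes rose, 2533 fell and 10458 did not pass, a call for 31.6%.

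The 5 lists called all moved down. Cholesterol synthesis had 12 of 21 down, 0 up and 9 not passed, with 12 down adjusted over the list alone (camera adjusted p = 4.36e-05; adjusted p = 0.91 with an estimated correlation), and Mvk, Nsdhl and Msmo1 fell by 1.43, 1.51 and 1.22 on the log2 scale. Secreted hepatocyte proteins had 11 of 20 down, 0 up and 9 not passed, with 11 down adjusted over the list alone (camera adjusted p = 6.83e-04; adjusted p = 0.813 with an estimated correlation), among them Serpina1b (log2 -3.27, SE 0.27), Serpina1a (-2.22), Ahsg (-1.79) and F9 (-1.34). Extracellular matrix and fibrosis genes had 9 of 25 down, 0 up and 16 not passed, with 10 down adjusted over the list alone (camera adjusted p = 0.0107; adjusted p = 0.91 with an estimated correlation). The collagen genes Col4a2, Col4a1, Col3a1 and Col5a2 fell by 2.31, 1.28, 2.75 and 2.19 on the log2 scale. Erythroid markers had 5 of 6 down and 1 not passed, with 5 down adjusted over the list alone (camera adjusted p = 0.00123; adjusted p = 0.813 with an estimated correlation). These were Hbb-bs (log2 -2.00), Hba-a1 (-1.89), Hbb-bt (-1.56), Alas2 (-1.09) and Klf1 (-2.09). Cell cycle genes had 9 of 28 down, 0 up and 19 not passed, with 10 down adjusted over the list alone (camera adjusted p = 0.00809; adjusted p = 0.91 with an estimated correlation; fry adjusted p = 0.0724). Thymidylate synthase, Tyms, fell by 1.67 (SE 0.21), the mitotic activator Cdc20 by 2.43 and the helicase subunit Mcm2 by 1.60 on the log2 scale. Cyclin B1, Ccnb1, with 2 counts in the P133 group, was 8.09-fold lower there (95% counting interval 2.05 to 69.9).

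Clock genes were among the largest single changes. The activator Arntl rose (log2 4.49, SE 0.50) and Nr1d1 and Dbp, which peak at another time of day, fell (log2 -4.35, SE 0.35, and -4.55, SE 0.87). The clock list did not pass (camera adjusted p = 0.715), but camera tests for 1 shared direction and these members moved both ways. Other rises included Mug2 (4.48, SE 0.26), Snhg11 (4.00, SE 0.24), Rn7s6 (3.64, SE 0.45), the heat shock gene Hspb1 (3.51, SE 0.54), Cabyr (3.44, SE 0.94) and Cfd, with 1 count in the untreated group, 486-fold higher (95% counting interval 86.5 to 19264). In P133 livers C1s2 and Serpina3h had 1 count each and were 339-fold (60.6 to 13414) and 233-fold (41.5 to 9207) lower. Ctse fell by 5.84 on the log2 scale, the metal-binding Mt1 by 5.25, the pentraxin Apcs by 4.70, Serpina3c by 3.85, and Prelid2 and Gipc1 by 3.77 each. Mug2, Ctse, Serpina3h and Serpina3c are among the 21 genes parted by group pair. Mcm2 did not pass with limma voom (adjusted p = 0.0523), a replicate block (0.052) or library totals (0.0741), nor did Alas2 and Ccnb1 with library totals (0.0967 and 0.0548). The calls of Cabyr, Mt1, Apcs and Ccnb1 ended with 1 mouse fewer, while their changes stayed near, at log2 2.96 (adjusted p = 0.0729) without P133 mouse 4, -5.12 (0.106) without P133 mouse 2, -4.67 (0.0555) without P133 mouse 4 and -2.34 (0.0667) without P133 mouse 4. Without untreated mouse 5 Mt1 stood at -3.15, Apcs at -3.05, Prelid2 at -2.97 and Arntl at 5.22, without untreated mouse 3 Cabyr at 4.36, without P133 mouse 4 Dbp at -5.52 and Mt1 at -5.98, and without P133 mouse 2 Ctse at -6.62. Cfd was 269-fold higher without P133 mouse 4. Cabyr also ended without any other mouse but untreated 3 and P133 mouse 3, Mt1 without untreated mice 1 or 3 or any P133 mouse, Apcs without P133 mice 2 or 3, and Ccnb1 without P133 mouse 3. Without untreated mouse 5, 11 lists were called in place of 5, and with library totals 7292 genes were called, 88.7% of them up. With an estimated correlation 0 lists passed after adjustment, 1 had an unadjusted camera p under 0.05, and fry called 9. In 100 random splits of the 9 mice, 89 called as many lists as the real split, and 4377 genes were called with replicate number as a block.

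Control ASO against P133 follows DEN livers from day 133 to day 260, with age and ASO injections joined. Oncofetal (15 of 23), cell cycle (14 of 28) and female-biased genes (15 of 21) were among those that rose, and male-biased (12 of 21), fatty acid oxidation (10 of 22), bile acid (10 of 19) and drug-metabolising cytochrome genes (13 of 20) among those that fell. The female-biased list alone, of 19, kept its call with an estimated correlation. Afp rose from 1.27 ± 0.986 CPM (SD, n = 4) to 183 ± 84.8 (n = 6; log2 7.10, SE 0.58, adjusted p = 4.57e-05), and Plk1, a mitotic kinase (ENSMUSG00000030867, chromosome 7), rose by log2 3.45 (SE 0.38, adjusted p = 4.23e-05). Cyp2b10, a target of the receptor CAR (ENSMUSG00000030483, chromosome 7), fell from 16.6 ± 3.05 to 0.489 ± 0.645 CPM (log2 -5.23, SE 0.54, adjusted p = 8.90e-05). In all, 2200 genes rose, 1931 fell and 11166 did not pass, a call for 27% of genes. With limma voom 1724 rose and 1954 fell, and with library totals 4840 were called, 79.6% of them up.

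Of 36 lists 19 were called, 11 up and 8 down. Female-biased genes had 15 of 21 up, 1 down (Cyp2b10) and 5 not passed, while adjusted over the list alone 16 rose and 2 fell (camera adjusted p = 1.13e-11), and kept the call with an estimated correlation (adjusted p = 0.0209). Cyp2a4, Cyp2b9 and Abcd2 rose by log2 6.70, 3.96 and 3.38. Oncofetal markers had 15 of 23 up, 1 down (Abcc4, log2 -1.29) and 7 not passed, while adjusted over the list alone 16 rose and 1 fell (camera adjusted p = 1.95e-12; adjusted p = 0.107 with an estimated correlation), among them Akr1c18 (log2 7.01), Tff3 (5.69) and the desaturase Scd2 (4.31). Cell cycle genes had 14 of 28 up, 1 down (Pcna, log2 -0.70) and 13 not passed, while adjusted over the list alone 16 rose and 1 fell (camera adjusted p = 6.41e-07; adjusted p = 0.192 with an estimated correlation), with Cdc20 and Cenpf up by log2 2.41 and 3.11. Ras-MAPK feedback genes had 7 of 11 up and 4 not passed, while adjusted over the list alone 7 rose and 1 fell (camera adjusted p = 4.16e-04; adjusted p = 0.165 with an estimated correlation), with Egr1, Dusp5 and Spry4 up by log2 4.85, 4.37 and 2.63. Immediate early genes had 10 of 19 up, 1 down (Myc, log2 -1.55) and 8 not passed, while adjusted over the list alone 14 rose and 1 fell (camera adjusted p = 6.41e-07; adjusted p = 0.283 with an estimated correlation), with Junb and Ier2 up by log2 2.55 and 2.06. Secreted proteins had 7 of 20 up, 1 down (Rbp4, log2 -0.58) and 12 not passed, while adjusted over the list alone 8 rose and 1 fell (camera adjusted p = 0.00314; adjusted p = 0.345 with an estimated correlation), with Apob and Serpina1a up by log2 2.26 and 2.20. Cholesterol synthesis had 8 of 21 up and 13 not passed, with 11 up adjusted over the list alone (camera adjusted p = 0.00211; adjusted p = 0.527 with an estimated correlation; fry adjusted p = 0.0577), with Sqle and Hmgcs1 up by log2 1.64 and 1.63.

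Bile duct markers had 4 of 10 up and 6 not passed, with 4 up adjusted over the list alone (camera adjusted p = 2.13e-04; adjusted p = 0.166 with an estimated correlation). They were Tspan8 (log2 6.69), Krt23 (3.47), Spp1 (2.98) and Cldn7. The last, at 0 counts in P133 livers, was 16.5-fold higher at 3 counts (lower 95% counting limit 13.3). Interferon response genes had 8 of 25 up and 17 not passed, with 9 up adjusted over the list alone (camera adjusted p = 0.00734; adjusted p = 0.493 with an estimated correlation), with Ifit1 and Usp18 up by log2 1.83 and 1.72. Extracellular matrix genes had 8 of 25 up, 1 down (Bgn, log2 -0.48) and 16 not passed, while adjusted over the list alone 9 rose and 2 fell (camera adjusted p = 0.013; adjusted p = 0.455 with an estimated correlation), with Col5a2 and the macrophage elastase Mmp12 up by log2 2.16 and 4.63. Neutrophil markers had 4 of 10 up and 6 not passed, with 4 up adjusted over the list alone (camera adjusted p = 0.0422; adjusted p = 0.383 with an estimated correlation). They were Lcn2 (log2 4.25), Cxcl2 (3.66), S100a8 (1.89) and Cxcr2. The last, at 0 counts in P133 livers, was 2.34-fold higher at 3 counts (lower 95% counting limit 1.76). With all groups in 1 fit Lcn2 (adjusted p = 0.0988), S100a8 (0.191) and Cxcr2 (0.0955) did not pass, nor did S100a8 (0.0514) and Cxcr2 (0.128) with a replicate block. The interferon call ended without control-ASO mouse 4 (adjusted p = 0.104), and the neutrophil call without P133 mice 2, 3 or 4 (0.0789, 0.0576 and 0.0532), control-ASO mice 1 or 6 (0.072 and 0.0585) with library totals (0.133) and without the mice of shifted clock genes (0.0923). The call of Cxcr2 ended without any 1 P133 mouse or control-ASO mice 2, 4 or 6 (adjusted p up to 0.0748).

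Among the lists that moved down, male-biased genes had 12 of 21 down, 0 up and 9 not passed, with 13 down adjusted over the list alone (camera adjusted p = 1.53e-10; adjusted p = 0.165 with an estimated correlation), with Ugt2b38 and Cyp2d9 down by log2 -3.47 and -1.82. Bile acid genes had 10 of 19 down and 9 not passed, with 10 down adjusted over the list alone (camera adjusted p = 4.08e-06; adjusted p = 0.283 with an estimated correlation), with Slco1a4 at log2 -2.00 and Akr1d1 at -1.13. Fatty acid oxidation genes had 10 of 22 down, 0 up and 12 not passed, while adjusted over the list alone 10 fell and 1 rose (camera adjusted p = 2.44e-05; adjusted p = 0.283 with an estimated correlation). Drug-metabolising cytochromes had 13 of 20 down, 3 up (Cyp2b9, Cyp2b13 and Cyp2a4, which the female-biased list also holds) and 4 not passed, while adjusted over the list alone 14 fell and 3 rose (camera adjusted p = 7.22e-05; adjusted p = 0.367 with an estimated correlation), with the receptor gene Nr1i2 at log2 -1.05. Pericentral genes had 5 of 18 down, 1 up (Rnf43, log2 1.58) and 12 not passed, with 5 and 1 adjusted over the list alone (camera adjusted p = 0.00211; adjusted p = 0.423 with an estimated correlation). The 5 were Cyp1a2 (log2 -2.48), Cyp27a1 (-1.71), Slc1a2 (-1.62), Glul, glutamine synthetase (-1.58), and Cyp2e1 (-1.36). Urea cycle genes had 8 of 20 down, 1 up (Agxt, log2 1.36) and 11 not passed, while adjusted over the list alone 10 fell and 1 rose (camera adjusted p = 0.00415; adjusted p = 0.493 with an estimated correlation), with Prodh at log2 -1.19 and Haao at -0.89. Gluconeogenesis and glycogen genes had 6 of 15 down, 0 up and 9 not passed, while adjusted over the list alone 8 fell and 1 rose (camera adjusted p = 0.0236; adjusted p = 0.367 with an estimated correlation), with glycogen phosphorylase Pygl at log2 -1.11 and Ppp1r3g at -2.45 (adjusted p = 0.125 with all groups in 1 fit). Stellate cell markers had 6 of 17 down, 1 up (Sod3, log2 0.87) and 10 not passed, while adjusted over the list alone 7 fell and 2 rose (camera adjusted p = 0.0321; adjusted p = 0.192 with an estimated correlation), with Vipr1 at log2 -1.88 and Angptl6 at -1.01. The stellate call ended without P133 mouse 3 (adjusted p = 0.0656) or control-ASO mouse 3 (0.0569).

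Tceal5 and Cyp3a16 had 0 counts in P133 livers, where 3 counts over the group correspond to 0.140 CPM. At 3 counts they were 107-fold (lower 95% counting limit 87) and 48.8-fold (39.5) higher in control-ASO livers. With 1 count in P133 livers, C1s2 was 405-fold (95% counting interval 72.6 to 16024), Erich4 363-fold (65.1 to 14357), Ly6k 209-fold (37.5 to 8284) and Alox5, the enzyme that starts leukotriene synthesis, 168-fold higher (29.9 to 6629). Bex1, with 2 counts, was 305-fold higher (84.4 to 2521). H19 rose by log2 8.33 (SE 1.05) and Cyp3a41a by 7.74 (SE 0.78). Besides Cyp2b10, the largest falls included Cabyr (log2 -4.91, SE 0.94), Odf3 (-4.64, SE 1.28), Nat8f5 (-4.21, SE 0.43), Mug2 (-3.41, SE 0.27), the PPAR alpha targets Cyp4a10 (-3.33, SE 0.44) and Cyp4a14 (-3.29, SE 0.51), Cfd (-3.32, SE 0.94) and Olig1 (-3.05, SE 0.39). Odf3 without P133 mouse 3 stood at -1.73 (adjusted p = 0.111), Cfd without P133 mouse 4 at -2.52 (0.106), and Ly6k ended without P133 mouse 1 (0.0789). The calls of Odf3 and Cfd also ended without single control-ASO mice (2 to 6 for Odf3, adjusted p up to 0.0625; 4 or 5 for Cfd, up to 0.0607), and that of Cfd without P133 mouse 2 (0.0599). With limma voom Cyp3a16 (adjusted p = 0.076), Ly6k (0.254), Odf3 (0.0843) and Cxcr2 (0.0613) did not pass. Without P133 mice, Cyp3a41a stood at 8.34 and Cxcl2 at 5.14 (mouse 1), Krt23 at 4.14 (mouse 3), and Spry4 at 4.25 and Mmp12 at 5.30 (mouse 4). Without control-ASO mouse 1 Cabyr and Cfd stood at -5.79 and -4.12, and without mouse 3 Cyp2b10 at -6.04. In 100 random splits of the 10 mice, 4 called as many lists as the real split. With replicate number as a block 2543 genes were called in place of 4131, on the 4 mice of each group with a shared number.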

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

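In this part the tests of Xist, of the mix at 1 common share of tumour, of splits of all 21 mice, of genes shared by 2 comparisons and of secreted and erythroid lists in both, and the removal of each mouse's trend on GC content, were chosen only after the result was seen.

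Oncofetal and female-biased genes were lower under Smyd3-ASO than under control ASO, by a mean log2 of -1.27 over 23 and -2.34 over 21 genes. A smaller share of tumour tissue in the Smyd3-ASO pieces would bring all genes of tumour tissue toward their normal level by 1 common share. Of 131 genes raised at least 8-fold in control-ASO livers over both untreated and P133 livers, 97 fell under Smyd3-ASO, 1 rose and 33 did not pass. Their median was log2 -2.75 (quartiles -3.79 and -1.42). With such genes picked on 3 control mice and scored against the other 3, the 95% interval of the change excluded the mix at 1 common share in 46.4% (38.6 to 51.9% over the ways of splitting), against up to 32.5% for changes between 3 and 3 of the Smyd3-ASO mice. This argues against a smaller share as the whole cause. Mice of both sexes are argued against by Xist, at 0 counts in all 21 mice, next to 179 to 1116 counts of the Y-linked Ddx3y.

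A difference that follows the pair of groups and not the ASO could add to this pattern, since P133 and untreated livers received no ASO. Between these 2 groups the female-biased genes changed by a mean log2 of -0.58 (95% interval over genes -1.22 to 0.07) and the oncofetal genes by -0.07 (-0.98 to 0.74). Both intervals are wide against the changes under Smyd3-ASO, so this stays open for either list. A smaller share of tumour as part of the change also stays open. So do unlabelled time of day, lower Smyd3, less advanced tumours and, with only 1 Smyd3-ASO, effects outside its target, untested.

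The genes parted by group pair put untreated with control-ASO livers and P133 with Smyd3-ASO livers, a pairing that no single treatment or age in the labels follows. The pairing was found before its genes were counted. Among 100 splits of the 21 mice 1, the real one, separated as many as 21 genes by a 2-fold gap (highest other 0), but a random split mixes whole groups and is bound to separate few. The 2 other pairings of the groups separated 2 and 0 genes. Time of day and sample exchange stay open. On 25 genes picked without them, untreated mouse 5 and control-ASO mice 1 and 2, of shifted clock genes, scored -0.103, 0.171 and 0.226. Scores run from 0 (own pair) to 1 (other pair). On genes picked without it, each of the 21 mice lay nearer to its own pair (highest 0.194). Such genes hold the 21 that part all mice, so the scores decide neither. A trend on GC content is argued against, as 18 of the 21 genes (85.7%) kept the gap without each mouse's trend.

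Genes that change between day 133 and day 260 and also respond to the Smyd3-ASO would give this pairing too, which was not tested and stays open. A variant between the strains or donors of the pairs stays open as well. Genes separated by the pairing made 57 neighbour pairs within 1 Mb where random genes made 25.84, a ratio of 2.21 that 0 of 10000 draws reached, but another pairing of the groups gave 4.17 and the third 1.01. How far the difference reaches also stays open. Changes of Smyd3-ASO over control ASO and of P133 over untreated, which share no mouse, correlated at Spearman 0.144 over all genes, and 13 of 100 splits of the ASO mice gave as much (highest other 0.195). In these comparisons 449 genes rose in both where independence gives 305.7, and 497 fell in both where it gives 326.5. Secreted protein genes (10 of 20 fell) and erythroid genes (3 of 6 fell, 1 rose) averaged log2 -0.73 and -0.99 under Smyd3-ASO. In P133 livers they averaged -0.88 and -1.51. Their list calls all ended with an estimated correlation. The Smyd3-ASO falls may belong to the group pair. Library batch was not labelled, so a batch along the group pair cannot be told from a difference between mice. Part of the 4000 calls between the ASO groups may come from either.

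The 7018 calls between control-ASO and untreated livers came with a trend on GC content (Spearman -0.158 between log2 change and GC). GC bias as the whole cause is argued against, as the number of calls without each mouse's trend was 97.8% of that with it. Whether a few abundant genes add to the calls stays open. Without the 50 most abundant genes the number of calls was 100% of that of the same genes before, but TMM scaling already trims such genes, so this removal moved nothing and tests nothing. With library totals in place of TMM 10723 genes were called, 93.6% of them up. Those 50 genes held 52.5% of counts in untreated, 36.1% in control-ASO and 28.1% in Smyd3-ASO livers. DEN, tumour tissue and the injections are joined in this design and stay open, untested.

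Single mice far from the others of their group were sought in 624 sets of values. A mouse was taken as far when its gap to the nearest mouse, divided by the range of the group, lay above Dixon's 95% value, which chance gives in about 1 in 20 groups. This held for 51 of 480 genes in groups (24 by chance) and 11 of 144 lists in groups (7.2 by chance). Ratios are given below, with log2 CPM for some. No explanation was tested for any of them.

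Untreated mouse 5 accounted for 15 of the genes and 5 of the lists. Its acute phase genes were high (ratio 0.92, mean log2 CPM 10.96 against 7.97 in the other 4), with Apcs at 0.754 and Saal1 at 0.773, as were neutrophil markers (0.819), endoplasmic reticulum stress (0.738), cholesterol synthesis (0.754) and Mcm2 (0.72). The clock list was low (0.719), with Dbp (0.883; log2 CPM 3.72 against 6.76) and Nr1d1 (0.745). Also low were Cyp4a12b (0.786), Ugt2b38 (0.855), Gbp11 (0.834), Rhbg (0.892), Nrep (0.804), Slco1a4 (0.741), Hsd3b7 (0.81), Hba-a1 (0.713) and Slco1a1 (0.717). Nctc1 was seen in this mouse alone of the group (ratio 1).

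In the other untreated mice, mouse 1 was high in Cyp3a41b (0.831) and Cyp2b13 (ratio 1). Mouse 3 was high in Cldn7 (1), Cfd (1) and Mir3092 (0.88), and low in Eda2r (0.819), Cdc20 (0.847) and p53 targets (0.747). Mouse 4 was low in Odf3 (0.743; log2 CPM 2.27 against 8.44).

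Among P133 mice, mouse 1 was high in Mvk (0.879) and Junb (0.848) and low in Ifi44 (0.935). It alone held counts of C1s2 (1 count), Bex1 (2) and Ly6k (1), each with a ratio of 1. Mouse 2 was high in Serpina1b (0.85) and Cyp2b9 (0.945), and mouse 3 in Erich4 (1) and Rnf43 (0.857). Mouse 4 was high in Serpina3h (1), Alox5 (1), fat and mesothelium markers (0.849; mean log2 CPM 2.18 against 0.73) and the clock list (0.923), and low in Cyp4a12b (0.88).

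Among control-ASO mice, mouse 1 was high in Saa3 (0.649), Tph1 (0.769) and Saal1 (0.696), and mouse 2 low in Mvk (0.636). Mouse 3 was high in Nctc1 (0.652) and low in Crym (0.63) and Cyp3a41a (0.629), and mouse 4 was high in Bst2 (0.847). Among Smyd3-ASO mice, mouse 1 was high in Mir675 (0.689) and low in cholesterol synthesis (0.634). Mouse 2 was low in Alas2 (0.727) and high in the list of epithelial-mesenchymal transition (0.737). Mouse 3 was high in Socs1 (0.706; log2 CPM 5.24 against 0.22), and mouse 4 was high in Mug2 (0.754) and low in Ly6k (0.651). Mouse 5 was low in T and NK cell markers (0.678), and mouse 6 in Bst2 (0.756; log2 CPM 5.19 against 8.52) and Junb (0.663).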

How the results depend on the processing

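Of the alternatives, 5 were added and the tests made with them were chosen only after the result was seen: library totals, protein-coding genes only, mice with high acute-phase genes left out, mice with shifted clock genes left out, and the GC trend removed. The planned fits on technical replicate 1 or 2 only were not run, since the deposited columns had merged them. No named gene that passed in either fit, and no called list or return score, changed direction under the alternatives that were run. Genes that passed in neither fit were not counted as turned. The balance of called genes did turn. The share that rose ran from 47.1 to 54.9% for Smyd3-ASO over control ASO (50.7% as reported), 49.1 to 93.6% for control ASO over untreated (51.6%), 48.0 to 91.4% for Smyd3-ASO over untreated (51.2%), 44.0 to 88.7% for P133 over untreated (47.7%) and 46.9 to 79.6% for control ASO over P133 (53.3%). The highest shares came from library totals. For the other turns, such as those under limma voom, the cause was not tested.

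For the counts of genes and lists and the return score, 244 alternative values were computed. In 220 the value held as defined for counts (within 1.5 times) or for the test, in 5 the return score newly passed, and in 19 a count moved further. For the 286 gene results named in the text, 6988 of 7198 values kept their side of the threshold, 208 no longer passed (88 of these with 1 mouse left out) and 2 newly passed. Direction was compared only where either fit passed. For the 49 called lists, 916 of 988 kept both and 72 no longer passed (14 with 1 mouse left out).

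Between Smyd3-ASO and control ASO 4000 genes were called, 3233 to 4446 with 1 mouse left out and 3073 to 4733 under the other alternatives. The other comparisons ran as follows, in the same order: control ASO over untreated 7018, 6208 to 6886, and 5712 to 10723. Smyd3-ASO over untreated gave 7288, 6434 to 7502, and 5791 to 10415, P133 over untreated 4839, 3977 to 4947, and 3451 to 7292, and control ASO over P133 4131, 3137 to 4318, and 2543 to 4840. Counts beyond 1.5 times came from library totals, with 10723 for control ASO over untreated and 7292 for P133 over untreated, and from the block on replicate number, with 2543 for control ASO over P133. Library totals moved the median of all genes by log2 0.85, 0.90 and 0.59 in the 3 comparisons with untreated livers, by 0.25 in control ASO over P133 and by 0.03 in Smyd3-ASO over control ASO, so their calls lean to 1 side by construction. The block for control ASO over P133 kept only the 4 replicate numbers that both groups share, so fewer mice and blocking cannot be told apart.

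Counts of lists moved more than counts of genes. With 1 mouse left out they ran from 5 to 10 for Smyd3-ASO over control ASO (7), 10 to 15 for control ASO over untreated (10), 8 to 10 for Smyd3-ASO over untreated (8), 5 to 11 for P133 over untreated (5) and 17 to 21 for control ASO over P133 (19). Camera with an estimated correlation called 1, 0, 0, 0 and 1 in that order. The correlation is estimated from these data, so these losses were not fixed in advance, and the preset of 0.01 may be too low. fry, which tests a list on its own, called 19 for control ASO over untreated, 23 for Smyd3-ASO over untreated and 9 for P133 over untreated. Without a filter 17 were called for Smyd3-ASO over control ASO, 17 for Smyd3-ASO over untreated and 9 for P133 over untreated. The block gave 13 for Smyd3-ASO over untreated and 10 for P133 over untreated. It also dropped Smyd3-ASO mouse 6 from the former and untreated mouse 5 from the latter. For P133 over untreated, 11 were called without untreated mouse 5, which is also the mouse that leaving out high acute-phase genes or shifted clock genes removes there, so these 3 alternatives are 1 fit. For the filter, the block and the mice left out, the cause was not tested.

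The return score of 0.17 (permutation p = 0.08) passed with a 2-fold minimum (0.257, p = 0.02), and the cause was not tested. With 1 Smyd3-ASO or untreated mouse left out (control mice, which it splits 3 and 3, were not) it ran from 0.126 to 0.2. It passed without Smyd3-ASO mice 1, 2 or 4 or untreated mouse 2. With no fold minimum it was 0.154 (p = 0.1), with a prior count of 5 0.15 (p = 0.1) and with the stricter filter 0.162 (p = 0.1).

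Small changes were mostly missed on simulated data with the depth and the spread of these mice, which were not varied apart. In the simulation 4.5% of 1.5-fold and 35.8% of 2-fold changes between the ASO groups were recovered, against 92.4% of 4-fold changes. Only 67, 67 and 66 genes were changed at these folds, against 4000 called in the data. Adjustment is stricter when few genes change, so recovery in the data may be higher. Thinned to the lowest total, 3073 genes were called between the ASO groups in place of 4000. Smyd3 itself rested on 0 to 13 counts per Smyd3-ASO mouse.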

Other observations

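Among lists that did not pass between Smyd3-ASO and control ASO, some members moved, named here after their values were seen. Of 26 macrophage markers 6 rose, 1 fell and 19 did not pass (camera adjusted p = 0.128), with C1qa up by log2 1.82, Itgam by 1.62 and Lyz2 by 1.07. T and NK cell markers had 4 of 11 up and 7 not passed (adjusted p = 0.124), which were Trbc2 (1.59), Il2rb (1.25), Ms4a4b (1.22) and Ccl5 (1.18). Endothelial markers had 7 of 23 down, 1 up and 15 not passed (adjusted p = 0.231), with Dnase1l3 at log2 -0.98, Fcgr2b at -0.85 and Stab2 at -0.70. Of 25 interferon response genes 6 rose, 2 fell and 17 did not pass (adjusted p = 0.129), with Gbp2 at 1.65 and Gbp3 at 1.46. Bile duct markers had 3 of 10 down, 1 up and 6 not passed (adjusted p = 0.0821), with Tspan8 at -3.35 and Krt23 at -3.27. Cell cycle genes went both ways, with 2 of 28 up (Mcm4, 1.15, and Pcna, 0.91), 2 down (Cdc20, -1.36, and Tpx2, -0.85) and 24 not passed (adjusted p = 0.128).

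In Smyd3-ASO over untreated livers, members of some immune cell lists moved without a call of the list. T and NK markers had 6 of 11 up, 1 down and 4 not passed (camera adjusted p = 0.0713), with Ms4a4b up by log2 4.43. B and plasma cell markers had 7 of 15 up, 1 down and 7 not passed (adjusted p = 0.105), with Jchain up by 3.54. Neutrophil markers had 5 of 10 up and 5 not passed (adjusted p = 0.0713), with Csf3r up by 2.91 and Il1b by 2.19. Macrophage markers went both ways, with 11 of 26 up, 6 down and 9 not passed (adjusted p = 0.246), Lyz2 at log2 1.83 and Csf1r at -1.73.

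The tests of random splits in this part were planned, and none of them was chosen only after the result was seen. For the number of genes called, chance is excluded in all 5 comparisons, as 1 of 100 splits, the real one, gave as many. The real count and the highest other were 4000 and 1040 for Smyd3-ASO over control ASO, 7018 and 4818 for control ASO over untreated, 7288 and 5237 for Smyd3-ASO over untreated, 4839 and 11 for P133 over untreated, and 4131 and 1631 for control ASO over P133. For the number of lists called, chance is not excluded in 4 comparisons, where 88, 70, 76 and 89 of 100 splits called as many (real 7, 10, 8 and 5; highest other 18, 22, 19 and 17). For control ASO over P133, 4 of 100 did (real 19, highest other 21), unadjusted over 5 tests, so chance stays open.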
